A study of Mus musculus with 9 samples.

How the data were processed

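Orthotopic pancreatic tumours of 3 mouse models were profiled as 9 droplet single-cell RNA libraries with 3′ v3.1 chemistry, per the labels' protocols, with 1 library per group. The deposited matrices held UMI counts per gene and cell, not normalized, per the file headers and the values. Per the file headers, the counts were made with Cell Ranger 5.0.0 for KPC1 (32285 genes), 7.0.1 for KPC3 (31053 genes) and 8.0.0 for KPC2 (33696 genes), while the submitters' processing notes named Cell Ranger 7.0.1 and the mm10 build. Whether intronic reads were counted is not stated. Values were therefore compared only within a model, and no genome positions were given. Barcodes were those the authors had deposited, and no cell annotation came with them.

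Cells with at least 500 UMIs, at least 250 genes and at most 20% mitochondrial counts were kept. Doublets were scored per library with the Scrublet method in scanpy 1.11.5, and the cells above the threshold that gave the expected rate of 0.8% per 1000 cells were removed. Scrublet's own threshold had marked under 0.5% of cells in 4 libraries, from 0.0616% to 0.165%, so that rate was adopted after the data were examined, and 3.54% to 9.07% of cells were removed. Within a model, counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 20 neighbours gave Leiden clusters at resolution 1 with random seed 1. KPC1 had 33 clusters, KPC3 32 and KPC2 31.

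Clusters were named from 22 marker sets fixed before the data were examined, and T-like cells were split again with 6 sets. The scoring thresholds were set after the data were examined: a mean marker z of at least 0.75, at least 3 detected markers and at least 30 cells. Sets within 0.5 of the best score were decided by markers among the top genes, and more top genes of another set, or low depth without an own marker there, barred a name. For T subclusters only the 6 T sets counted, so 3 led by acinar or macrophage genes kept a T name. Clusters that failed stayed unnamed, 6, 4 and 4 of those in KPC1, KPC3 and KPC2, and shares may depend on these rebuilt names. Immune shares were taken over all immune classes, with exact binomial intervals, and differences of shares with 95% counting intervals.

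Counts were summed over the cells of a class in a library and scaled to CPM. A fold was the ratio of CPM, with an exact interval for the ratio of 2 Poisson counts, and a library with 0 counts was set at 3 counts. With 1 library per group no test across libraries was possible and no p-value was computed. In all, 27 gene lists were fixed before the data were examined: RAS-MAPK output, cell cycle, MHC class I, MHC class II, interferon response, death receptor, tumour cytokine, glycolysis and hypoxia, classical epithelial, mesenchymal, myofibroblastic, inflammatory and antigen-presenting CAF, inflammatory and tissue-repair macrophage, neutrophil activation and maturation, cytotoxic effector, T cell checkpoint, costimulation, naive and memory, and regulatory T, B cell activation, dissociation stress, acinar RNA, haemoglobin, and sex of the mouse. Some were assigned to further classes later. A list's value was the median log2 fold over members with at least 10 counts in both libraries together, in classes with at least 20 cells, with an interval from 2000 Poisson redraws. Its percentile among 10000 random lists matched over 20 expression bins describes these libraries only. The median gene was the median log2 fold over genes with at least 50 counts in both libraries.

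Genes named outside the lists followed a rule fixed before the data were examined. In epithelial-like, fibroblast-like, macrophage-like, neutrophil-like and T-like cells (KPC2: T-like, macrophage-like, neutrophil-like and B-like) with at least 100 cells in each library, the 3 highest and 3 lowest folds were named. Eligible genes had at least 50 counts in 1 library, an interval wholly beyond 2-fold, and a CPM in the class of at least 0.5 of their highest in any class with at least 100 cells in the pair, so RNA of smaller classes, such as plasma-like cells in KPC2, was not left out. Mitochondrial, ribosomal, haemoglobin, antigen receptor, sex-linked, Malat1 and predicted genes were left out. In lists described by members, up to 4 with the largest folds and at least 20 counts were named, with those against the median. Ctla4, Pdcd1, Kras, Fas and Fasl were given whatever their values. Which lists were described by members, and the limit of 1 for medians in other classes, were set after the data were examined.

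Alternatives fixed before the data were examined were median-of-ratios scaling, CPM without mitochondrial, ribosomal and haemoglobin genes, Leiden resolution 2, thinning each cell to 1000 UMIs, a stricter filter (at least 1000 UMIs, at most 10% mitochondrial), doublets kept, classes assigned cell by cell, list members with at least 50 counts, and no filter on low counts. Added afterwards were T-like cells without naive-like and unnamed subclusters, other sets of epithelial clusters, CD8-like cells without subclusters with at least 5 acinar genes among their 10 leading genes, T-like shares without B-like and plasma-like cells, and cells split by Xist and Y-linked UMIs. Fold and interval code was tested on simulated counts with known folds, first after an initial run on the real counts. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.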

Results

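The series profiled pancreatic tumours of mice by droplet single-cell RNA sequencing (10x Chromium, 3′ chemistry), and its title named the combination of KRAS inhibitors with checkpoint immunotherapy as its subject. Tumour cells were implanted into the pancreas from 3 lines called KPC1, KPC2 and KPC3, all from mice with a Kras G12D allele and altered Trp53. MRTX1133 binds KRAS G12D, and RMC6236 binds RAS proteins in their active state. Antibodies against CTLA4 and PD1 block receptors that restrain T cells. KPC1 gave 2 libraries of live cells after 2 weeks (vehicle, MRTX1133). KPC3 gave 3 libraries of live cells after 10 days (anti-CTLA4, MRTX1133, and MRTX1133 with anti-CTLA4), with no vehicle library. KPC2 gave 4 libraries of sorted CD45+ cells after 2 weeks (vehicle with isotype antibody, RMC6236, RMC6236 with anti-CTLA4, and RMC6236 with anti-PD1).

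Each group was 1 library, so no difference had a replicate check, and intervals (95%) covered counting error only. The 9 libraries held 69041 barcodes, of which 60266 passed the cell filter and 56932 were analysed after 3334 marked doublets were removed. Expression in a cell class was the sum of its counts, scaled to a fixed total (CPM). Gene values were log2 folds of CPM, first library over second. A named list member without an interval had one that lay wholly on 1 side of 0 and spanned less than 2 log2 units. Genes named outside the lists were picked by a fixed rule and had intervals wholly beyond 2-fold. Their values were folds, or log2 folds with intervals where the lower library held 1 to 3 counts, and “at least” marks a library with 0 counts, set at a floor of 3. List values were medians over members with their intervals, and values called relative were taken against the median gene of the class, given where that gene lay more than 0.1 from 0. In each library pair, members were named for some lists and others were given as medians. Lists with medians within 1 of 0 were left out of these Results for dissociation stress and, with some exceptions, outside epithelial-like and T-like cells, where dissociation stress was not given.

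In the libraries KPC1_Veh and KPC1_MRTX1133, total counts were 142693612 and 100424050.0, median counts per barcode were 8501 and 5820.0, and 93.7% and 81.7% of barcodes passed the filter. Analysed cells numbered 10774 and 7181. Acinar RNA, digestive enzyme transcripts of the exocrine pancreas, took 6258.76 and 1042.22 CPM of all cells and 2741.51 and 160.9 CPM of T-like cells. Haemoglobin took 336 and 603 CPM, and genes of dissociation stress 6072.49 and 2057.44 CPM of all cells. Xist, the transcript of the inactive X chromosome, was seen in 94.0% and 91.8% of T-like cells. Y-linked transcripts were seen in 0 of 184 T-like cells of the vehicle library, which allows up to 1.98%, and in 0.0677% of those of the MRTX1133 library. Cells of clusters left unnamed were 18.2% and 7.17% of cells.

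The KPC1 comparison asked how tumours under the KRAS G12D inhibitor differed from vehicle tumours. T-like cells were 51.3% of immune cells (50.05 to 52.6, 2953 of 5751) in the MRTX1133 library and 3.87% (3.34 to 4.45, 184 of 4759) in the vehicle library. Macrophage-like cells were 2.21% against 69.7%, and B-like cells 30.3% against 0.315%. Epithelial-like cells of the MRTX1133 library had higher interferon response and antigen presentation genes and lower cell cycle genes. Fas, a death receptor, was at 1.89 (1.503 to 2.29) in those cells, and Kras at 0.15 (0.10 to 0.20).

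The T-like share differed by 47.5 percentage points (46.1 to 48.9), a 13.3-fold ratio. Per myeloid cell, CD8-like T cells were 23.9-fold as many (19.0 to 30.1). Of the 119 vehicle CD8-like cells, 116 lay in a T subcluster led by acinar genes, which held 31 of the 340.0 with MRTX1133. Without it the ratio was 863-fold (276 to 2699.5), from 3 vehicle cells. Of T-like cells, the MRTX1133 library held 11.5% CD8-like, 11.5% CD4-like, 9.21% regulatory, 18.05% naive-like and 38.7% unnamed cells. Unnamed subclusters of 631 and 272 cells had Cd8b1 at 923 and 584 CPM, so CD8-like cells were not all cells with CD8 transcripts, and Cd8a in T-like cells was at −0.59 (−0.72 to −0.45). The vehicle library held 64.7% CD8-like, 14.7% regulatory and 1.63% unnamed cells, with 0 of 184 naive-like (up to 1.98%). Monocyte-like cells were 2.68% against 10.5% of immune cells, neutrophil-like 3.62% against 5.84%, dendritic-like 3.41% against 7.44%, plasma-like 4.29% against 1.37% and natural killer-like 1.65% against 0.273%. Of all cells, epithelial-like cells were 8.37% against 15.9%, fibroblast-like 1.35% against 14.7%, endothelial-like 1.504% against 4.38% and acinar-like 0.279% against 1.73%. These shares were taken over live cells without a further sort, and median counts per barcode and the passing share were lower in the MRTX1133 library, but its T-like, macrophage-like and epithelial-like cells were deeper (medians 5971, 12588 and 32891 against 4211, 7041 and 18850.0 counts).

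**Figure D1:**
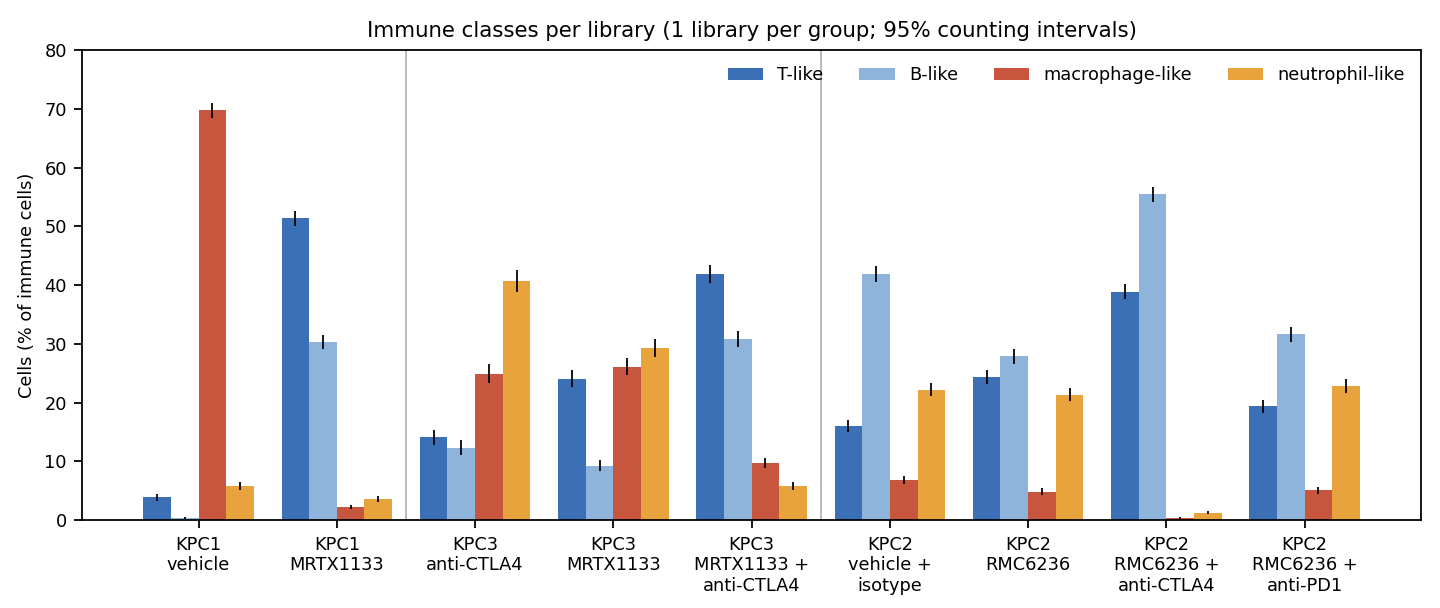
Bars give T-like, B-like, macrophage-like and neutrophil-like cells as a percentage of immune cells (y axis) in each of the 9 libraries, with 95% counting intervals. T-like cells ranged from 3.87% in KPC1 vehicle to 51.3% in KPC1 MRTX1133, and the KPC2 libraries were sorted for CD45.

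Epithelial-like cells numbered 601 and 1711 in the KPC1 pair. Cluster 10, with the cycling genes Cenpf and Birc5 among its leading genes, held 9.15% and 32.3% of them, which bears on the cell cycle list, and the median gene stood at 0.29 between them. 9 of 15 RAS-MAPK output genes, which are transcribed when the pathway below KRAS is active, were lower, median −0.16 (−0.29 to −0.01, −0.45 relative). Ier3 at −1.43, Dusp5 at −1.21, Fosl1 at −1.17 and Epha2 at 0.90 had the largest folds, and against the median stood Spry2 at 0.56, Spry4 at 0.01 (−0.24 to 0.26), Spred1 at 0.61, Spred2 at 0.55 and Phlda1 at 0.15. The median lay at percentile 0.75 of 10000 random lists. 18 of 22 cell cycle genes were lower, median −0.51 (−0.58 to −0.45, −0.80 relative). Top2a at −1.35, Bub1 at −0.96, Cenpf at −0.77 and Birc5 at −0.72 differed most, and Cdk1 at 0.46, Cdc20 at 0.24, Pcna at 0.63 and Mcm2 at 0.16 went against the median. All 11 MHC class I genes, which present peptides to CD8 T cells, were higher, median 1.30 (1.21 to 1.49, 1.01 relative). All 7 MHC class II genes were higher, median 1.57 (1.48 to 1.64, 1.27 relative). All 22 interferon response genes were higher, median 1.15 (1.09 to 1.23, 0.86 relative). Ifit1 at 2.21, Irgm1 at 2.02, Gbp4 at 1.87 and Gbp5 at 1.77 were furthest from 0. All 8 death receptor genes were higher, median 0.49 (0.43 to 0.60, 0.20 relative). 8 of 14 tumour cytokine genes were higher, median 0.13 (0.00 to 0.38, but −0.16 relative). 11 of 15 glycolysis and hypoxia genes were higher, median 0.08 (0.07 to 0.13, but −0.21 relative). 10 of 13 classical epithelial genes were higher, median 0.59 (0.52 to 0.67, 0.30 relative). 6 of 11 mesenchymal genes were higher, median 0.05 (−0.18 to 0.09, but −0.24 relative, mean −0.15). 11 of 12 dissociation stress genes were lower, median −1.10 (−1.15 to −1.04, −1.39 relative). By the fixed rule, Lypd8 (at least 47.7-fold), Ccl20 (log2 5.43, 3.51 to 8.51), a chemokine, and S100g (30.9-fold) were higher. Muc6, a gastric mucin (log2 −5.38, −10.70 to −2.85), Car1 (at least 15.8-fold) and Pitx1 (11.5-fold) were lower. Thinning every cell to 1000 counts put the RAS-MAPK output median at −0.36, and tumour cytokine and glycolysis and hypoxia medians turned sign to −0.14 and −0.01.

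Fibroblast-like cells of the vehicle library came from clusters 7 (878) and 8 (705), those of the MRTX1133 library from cluster 8 (86 of 97). 9 of 11 myofibroblastic genes, which mark contractile, matrix-producing cancer-associated fibroblasts (CAFs), were lower, median −1.49 (−1.71 to −1.34, −1.63 relative). 8 of 12 inflammatory CAF genes were higher, median 1.36 (1.29 to 1.42, 1.22 relative). Kras stood at −0.04 in these cells.

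Macrophage-like cells of the vehicle library came from clusters 0 (1608, led by Ccl8) and 1 (1510.0, led by Mmp12), those of the MRTX1133 library mostly from cluster 1 (106 of 127). 8 of 14 tissue-repair macrophage genes were higher, median 0.07 (−0.45 to 0.15, mean −1.004). The 6 lower genes were Il10 at −4.46 (−7.51 to −2.61), Cd163 at −4.30 (−5.51 to −3.32), Folr2 at −2.88, Ccl8 at −2.87, Mrc1 at −2.07 and Chil3 at −2.54. Nos2, the inducible nitric oxide synthase (9.68-fold), Tnfrsf9 (6.43-fold) and Slc7a2, an arginine carrier (5.86-fold), were higher. By the rule, Il10, Cd163 and C6 (log2 −4.24, −6.52 to −2.69) were lower. In monocyte-like cells, medians were −2.06 (−2.497 to −1.81, −2.18 relative) for inflammatory macrophage (8 of 10 lower) and 1.10 (1.01 to 1.14, 0.98 relative) for MHC class II (7 of 7 higher).

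Neutrophil-like cells numbered 208 and 278. The median was 1.05 (0.77 to 1.38) for interferon response (17 of 22 higher). Ly6i (13.8-fold), Socs1, a brake on cytokine signalling (12.04-fold), and Tap2 (10.98-fold) were higher. Elane (at least 130.3-fold), Ctsg (at least 46.9-fold) and Ms4a3 (log2 −4.60, −6.91 to −2.999), genes of neutrophil precursors, were lower.

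T-like cells of the MRTX1133 library came mainly from clusters 5 (1099), 6 (855) and 11 (604), those of the vehicle library from clusters 17 (84) and 6 (51), and the median gene stood at −0.26. 13 of 14 cytotoxic effector genes were lower, median −1.37 (−1.48 to −1.15, −1.10 relative). Gzmk at −2.22, Klrg1 at −1.95, Gzmb at −1.72 and Prf1 at −1.58 lay furthest from 0, and Tnf at 0.88 (−0.27 to 2.34) lay against the median. 9 of 10 T cell checkpoint genes were lower, median −1.77 (−1.88 to −1.57, −1.51 relative). 7 of 9 naive and memory T genes were higher, median 2.04 (1.78 to 2.34, 2.31 relative). Lef1 at 3.88, Tcf7 at 2.71, Igfbp4 at 2.30 and Sell at 2.27 had the largest folds, and Ccr7 at −0.40 and Il7r at −0.01 (−0.18 to 0.16) lay against the median. 10 of 11 regulatory T genes were lower, median −1.27 (−1.54 to −1.01, −1.01 relative). Medians were −0.15 (−0.42 to 0.15, but 0.11 relative) for costimulation (4 of 7 lower), 0.41 (0.15 to 0.60, 0.67 relative) for interferon response (14 of 22 higher), −0.95 (−1.10 to −0.79, −0.69 relative) for cell cycle (19 of 22 lower) and −1.41 (−1.59 to −1.28, −1.15 relative) for dissociation stress (12 of 12 lower). Ctla4 was at −1.48 (−1.66 to −1.30), Pdcd1, which encodes PD1, at −1.77 (−1.99 to −1.54) and Fasl at −1.39 (−1.85 to −0.90). Dtx1 (log2 5.28, 3.42 to 8.32), Aff3 (log2 4.62, 2.14 to 9.93) and Vipr1 (log2 4.33, 1.85 to 9.64) were higher, and Ccl1 (7.87-fold), Rgs16 (6.30-fold) and Odc1, of polyamine synthesis (5.36-fold), were lower. With naive-like and unnamed T subclusters left out, a choice made after seeing the data, the cytotoxic effector median was −0.55, checkpoint −0.84, naive and memory 1.04 and regulatory T −0.23.

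**Figure D2:**
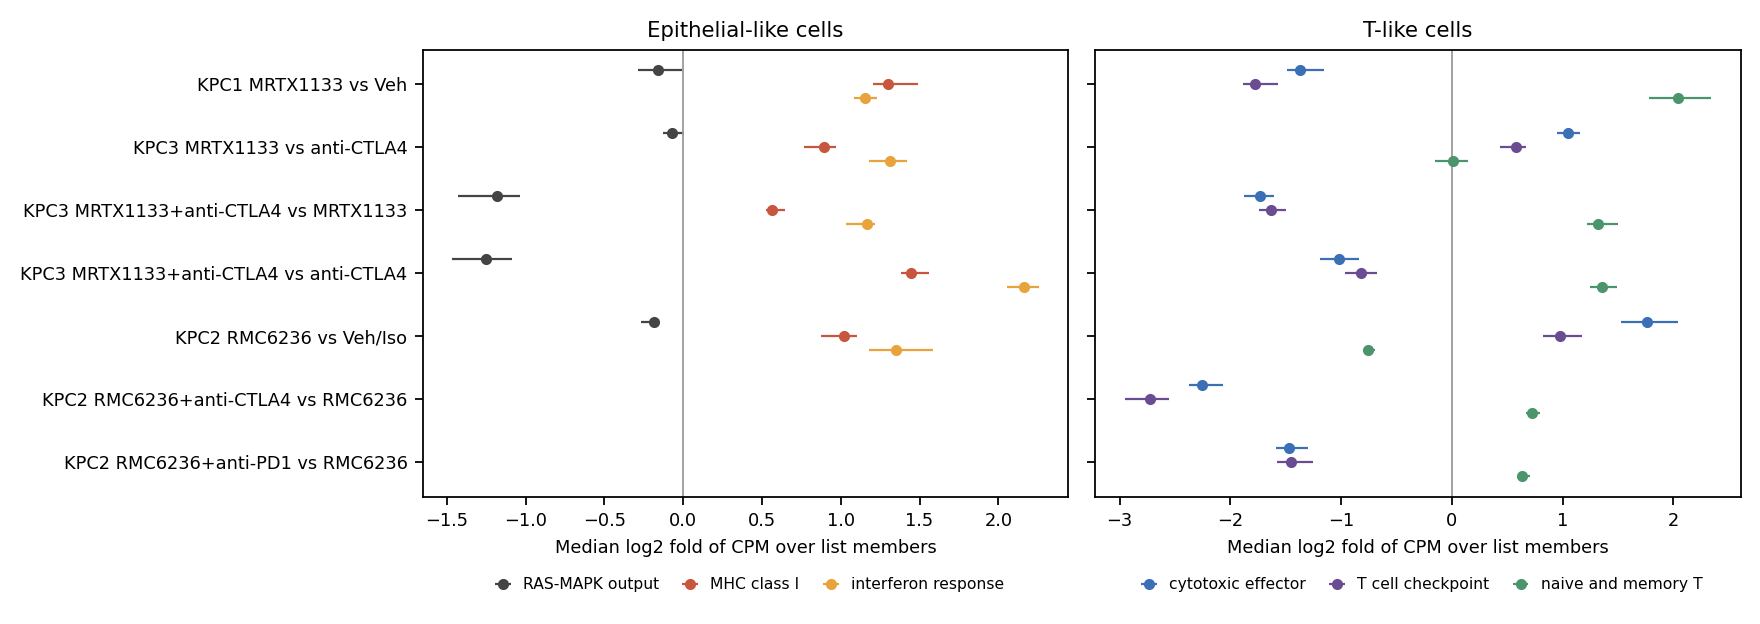
Points give the median log2 fold of CPM over the members of each list (x axis) in epithelial-like and T-like cells, per comparison, with 95% counting intervals. The cytotoxic effector median in T-like cells was 1.77 for KPC2 RMC6236 over vehicle and −2.26 with anti-CTLA4 added.

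In KPC3, the libraries KPC3_antiCTLA4, KPC3_MRTX1133 and KPC3_MRTX1133_antiCTLA4 held total counts of 108432347, 85686451 and 58360169, with median counts per barcode of 9766, 9099 and 2921.5. The share of barcodes that passed the filter was 87.6%, 91.9% and 62.9%, and 32.7% of barcodes of the combination library held fewer than 1000 counts. Analysed cells numbered 4684, 4692 and 6345. Acinar RNA took 246.1, 2008.64 and 85815.7 CPM of all cells and 109.3, 841.6 and 7192.16 CPM of T-like cells. Haemoglobin took 16535.0, 1049.73 and 32182.4 CPM, and dissociation stress genes 6723.41, 6458.08 and 2386.42 CPM. Y-linked transcripts were seen in 88.6% of T-like cells with anti-CTLA4 (median 8910.0 counts) and 83.8% with MRTX1133 (median 8070.0), with Xist in 0.260% and 0.120%. In the combination library, Xist was seen in 73.7% of T-like cells (median 4147 counts) and Y-linked transcripts in 0.0562%. Epithelial-like cells of the first 2 libraries held Y-linked transcripts in 11.6% and 10.8% of cells (medians 30627 and 28695) and Xist in 0.284% and 0.515%, and those of the combination library held Xist in 72.8%, or in 8.33% of the 96 outside the duct-like cluster. Hosts differed in sex by these transcripts. Whether labels were exchanged is not known, and that would change what each KPC3 comparison means. Unnamed clusters held 5.76%, 3.92% and 3.12% of cells.

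MRTX1133 against anti-CTLA4 in KPC3 set one single agent beside the other, as no vehicle library was present. T-like cells were 24.0% of immune cells (832 of 3465) with MRTX1133 and 14.1% (385 of 2737) with anti-CTLA4, a difference of 9.95 points (8.003 to 11.9). CD8-like cells were 48.6% against 15.3% of T-like cells, and 6.40-fold as many per myeloid cell (4.84 to 8.48), with Cd8a in T-like cells at 1.17 (1.05 to 1.29). Cytotoxic genes were higher in T-like cells, and epithelial-like cells had higher interferon response, antigen presentation and cell cycle genes and lower glycolysis genes. Kras was at −0.12 (−0.19 to −0.05) and Fas at 0.51 (0.17 to 0.84) in epithelial-like cells.

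Neutrophil-like cells were 29.3% against 40.7% of immune cells, macrophage-like 26.1% against 24.9%, B-like 9.29% against 12.3%, plasma-like 2.48% against 1.06%, natural killer-like 3.41% against 2.37% and dendritic-like 5.11% against 4.35%. CD4-like, regulatory, naive-like and unnamed cells were 11.3%, 19.4%, 16.9% and 3.73% of T-like cells with MRTX1133 and 13.5%, 17.4%, 19.0% and 34.5% with anti-CTLA4. Of the CD4-like cells, 90 of 94 and 48 of 52 lay in a subcluster with more Cd8b1 (242 CPM) than Cd4 (154 CPM), so that name is uncertain. Of all cells, epithelial-like cells were 8.27% against 22.6%, fibroblast-like 10.5% against 5.10% and erythroid-like 0.213% against 1.96%.

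Epithelial-like cells numbered 388 and 1057, mainly of cluster 3. 9 of 15 RAS-MAPK output genes were lower, median −0.07 (−0.13 to 0.00). Dusp4 at −1.13, Ier3 at −0.80, Spry4 at −0.78 and Dusp5 at −0.77 differed most, and Etv4 at 0.20, Etv5 at 0.40, Phlda1 at 0.60, Epha4 at 0.41, Ccnd1 at 0.61 and Fosl1 at 0.02 (−0.09 to 0.13) had the sign opposite to the median. The median lay at percentile 31.2 of 10000 random lists, and thinned to 1000 counts it was −0.29. 20 of 22 cell cycle genes were higher, median 0.96 (0.88 to 1.01). All 11 MHC class I genes were higher, median 0.89 (0.77 to 0.97). All 7 MHC class II genes were higher, median 1.31 (1.25 to 1.43). 17 of 22 interferon response genes were higher, median 1.31 (1.18 to 1.42). 11 of 13 tumour cytokine genes were higher, median 0.51 (0.41 to 0.69). All 15 glycolysis and hypoxia genes were lower, median −0.61 (−0.67 to −0.56). Medians were 0.22 (0.08 to 0.31) for death receptor (6 of 8 higher), −0.04 (−0.07 to −0.01, mean 0.10) for classical epithelial (7 of 13 lower) and 0.16 (0.02 to 0.29) for mesenchymal (6 of 11 higher). With thinning, the classical and mesenchymal medians turned sign to 0.08 and −0.17. Acta1 (log2 9.13, 7.58 to 11.41), Myl1 (log2 7.94, 6.37 to 10.22) and Ckm (61.2-fold), genes of skeletal muscle, were higher. Svs5, Svs4 and Svs2, which encode seminal vesicle secretions, were lower in the MRTX1133 library, at least 5735-fold, at least 2775-fold and at least 1373-fold, with 0 counts there and 49770.0, 24085 and 11911 counts with anti-CTLA4.

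Fibroblast-like cells came mainly from cluster 11 with MRTX1133 (351 of 493) and cluster 9 with anti-CTLA4 (165 of 239). Serpinb2 (169.5-fold), Akr1c18, of progesterone breakdown (log2 7.14, 4.65 to 12.45), and Angptl1 (110.3-fold) were higher, and Plcxd3 (37.7-fold), the acute phase gene Saa2 (26.4-fold) and Trpc6 (15.7-fold) were lower. Kras was at 0.32 in these cells.

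Macrophage-like cells numbered 905 and 681. Mt3 (5.20-fold), Ly6i (3.74-fold) and Gbp2b (3.26-fold) were higher, and Reg3b (78.3-fold), Pnlip (53.9-fold), genes of the exocrine pancreas, and Frg2f1 (9.43-fold) were lower. Neutrophil-like cells came mainly from cluster 5 with MRTX1133 (565 of 1015) and cluster 8 with anti-CTLA4 (585 of 1114). 20 of 22 interferon response genes were higher, median 1.08 (0.94 to 1.19). The acinar genes Sycn (13.8-fold), Ctrb1 (13.6-fold) and Rnase1 (13.6-fold) were higher, beside the higher acinar RNA of that library, and Gal (8.004-fold), Slc18a1 (6.68-fold) and Efcab8 (6.32-fold) were lower.

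T-like cells came mainly from cluster 4 in each library (471 of 832 and 172 of 385). 13 of 14 cytotoxic effector genes were higher, median 1.05 (0.95 to 1.16). Ccl3 at 2.14, Ccl4 at 2.06, Gzma at 1.497 and Klrd1 at 1.26 were furthest from 0, and Tnf at −1.13 had the sign opposite to the median. 9 of 10 T cell checkpoint genes were higher, median 0.58 (0.43 to 0.67). 5 of 7 T cell costimulation genes were higher, median 0.46 (0.36 to 0.55). Medians were 0.01 (−0.15 to 0.14) for naive and memory T (5 of 9 higher), 0.21 (0.15 to 0.35) for regulatory T (9 of 11 higher), 0.27 (0.10 to 0.45) for interferon response (15 of 22 higher) and 0.19 (−0.09 to 0.40) for cell cycle (13 of 21 higher). Ctla4 was at 0.33 (0.25 to 0.40), Pdcd1 at 0.66 (0.53 to 0.78) and Fasl at 0.47 (0.26 to 0.68). The chemokine gene Ccl1 (13.1-fold) and the acinar genes Ctrb1 (12.98-fold) and Clps (12.7-fold) were higher, and Gzme, a granzyme (62.0-fold), Zfp804b (17.5-fold) and Il23r (10.3-fold) were lower. Without naive-like and unnamed subclusters the cytotoxic effector median was 0.65 and checkpoint 0.39, and the naive and memory and regulatory T medians turned sign to −0.47 and −0.27. B-like cells came mainly from cluster 15 with MRTX1133 (272 of 322) and cluster 19 with anti-CTLA4 (250 of 336). The median was 1.84 (1.34 to 2.02, 1.96 relative) for cell cycle (21 of 22 higher). Fas was at 0.98 (−0.06 to 2.09) there.

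Adding anti-CTLA4 to MRTX1133 in KPC3 was compared with MRTX1133 alone. T-like cells were 41.9% of immune cells (1779 of 4250) against 24.0%, a difference of 17.8 points (15.8 to 19.9), and naive-like cells were 37.0% against 16.9% of T-like cells. In T-like cells, cytotoxic effector and checkpoint genes were lower and interferon response genes higher in the combination library. Epithelial-like cells, most of them in a duct-like cluster of the combination library, had lower RAS-MAPK output, mesenchymal and glycolysis genes. Fas was at 0.84 (0.42 to 1.25) and Kras at −0.19 (−0.30 to −0.08), but Kras at 0.34 (0.22 to 0.46) without that cluster.

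CD8-like cells were 12.4% against 48.6% of T-like cells, and 1.60-fold as many per myeloid cell (1.33 to 1.93), with Cd8a in T-like cells at −1.30 (−1.39 to −1.21). A naive-like subcluster of 293 cells, all of the combination library, had Cd8b1 at 616 CPM, against 546 in the largest CD8-like one, so CD8-like cells were not all cells with CD8 transcripts. Of the 221 CD8-like cells of the combination library, 163 lay in a T subcluster led by acinar genes, and without it the ratio turned to 0.421-fold (0.315 to 0.562). CD4-like, regulatory and unnamed cells were 10.96%, 14.2% and 23.7% of T-like cells in the combination library, and 164 of its 195 CD4-like cells lay in a subcluster that held 4 of those with MRTX1133. B-like cells were 30.8% against 9.29% of immune cells, plasma-like 7.06% against 2.48%, macrophage-like 9.69% against 26.1%, neutrophil-like 5.76% against 29.3%, natural killer-like 1.88% against 3.41% and dendritic-like 2.45% against 5.11%. Of all cells, acinar-like cells were 14.8% against 0.149%, epithelial-like 5.67% against 8.27%, fibroblast-like 5.78% against 10.5% and erythroid-like 1.39% against 0.213%. Depth per barcode and the passing share were lower in the combination library and bear on these shares.

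Of 360 epithelial-like cells of the combination library, 264 lay in the duct-like cluster 17, while 271 of 388 cells with MRTX1133 lay in cluster 3, and the median gene stood at 0.19. 14 of 15 RAS-MAPK output genes were lower, median −1.18 (−1.43 to −1.03, −1.37 relative). Dusp4 at −2.95, Fosl1 at −2.93, Spry4 at −2.49 and Dusp5 at −2.41 lay furthest from 0, and against the median stood Ccnd1 at 0.07 (−0.01 to 0.15). 20 of 22 interferon response genes were higher, median 1.16 (1.03 to 1.22, 0.98 relative). All 11 MHC class I genes were higher, median 0.56 (0.53 to 0.65, 0.37 relative). All 7 MHC class II genes were higher, median 0.63 (0.53 to 0.71, 0.44 relative). All 15 glycolysis and hypoxia genes were lower, median −0.87 (−0.93 to −0.77, −1.06 relative). 9 of 10 mesenchymal genes were lower, median −2.18 (−2.55 to −1.68, −2.37 relative). 10 of 12 tumour cytokine genes were lower, median −1.42 (−1.87 to −1.07, −1.61 relative). Medians were −0.50 (−0.62 to −0.39, −0.69 relative) for cell cycle (20 of 22 lower), −0.02 (−0.16 to 0.19, −0.21 relative, mean 0.10) for death receptor (4 of 8 lower) and −0.41 (−0.44 to −0.29, −0.60 relative) for classical epithelial (8 of 13 lower). Without cluster 17, a choice made after seeing the data, medians were −1.32 for RAS-MAPK output (Ccnd1 −1.39), 1.04 and 1.02 for MHC class I and II, 1.52 for interferon response, −0.45 for glycolysis and hypoxia, −1.72 for mesenchymal and −1.03 for tumour cytokine, and cell cycle and classical medians turned sign to 0.08 and 0.14. Pah (log2 9.42, 6.93 to 14.73), Chst9 (log2 8.84, 6.97 to 11.89) and Lamc3 (log2 8.50, 6.01 to 13.82) were higher, and Muc5b (log2 −7.34, −12.64 to −4.85), Ndst3 (log2 −6.91, −12.22 to −4.42) and Myl1 (log2 −6.78, −12.09 to −4.29) were lower.

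Fibroblast-like cells of the combination library came from cluster 9 (340 of 367) and those with MRTX1133 from cluster 11 (351 of 493). 10 of 11 myofibroblastic CAF genes were lower, median −2.10 (−2.24 to −1.94, −2.29 relative). 6 of 7 antigen-presenting CAF genes were lower, median −1.66 (−1.86 to −1.47, −1.85 relative). Akr1cl (at least 782-fold), Cyp11a1, of steroid hormone synthesis (122-fold), and Apoa1 (90.0-fold) were higher. Serpinb2 (at least 201-fold), Tnn (log2 −6.83, −12.13 to −4.34) and Defb48 (log2 −6.74, −12.05 to −4.26) were lower, and Kras was at 0.60.

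12 of 14 tissue-repair macrophage genes were lower, median −1.12 (−1.25 to −0.92). All 7 MHC class II genes of macrophage-like cells were higher, median 1.28 (1.20 to 1.30). The lysozyme gene Lyz1 (41.5-fold), Retnla (30.1-fold) and Clec4b1 (15.5-fold) were higher, and Il10 (31.3-fold), Mt3 (log2 −4.76, −10.08 to −2.25) and Wdr90 (log2 −4.14, −9.47 to −1.62) were lower. Neutrophil-like cells came mainly from cluster 7 in the combination library (149 of 245) and cluster 5 with MRTX1133 (565 of 1015). Stfa1 (4.29-fold), Oasl1 (4.23-fold) and Slc36a3os (3.94-fold) were higher, and Elane (at least 35.4-fold), the heat shock gene Hspa1a (17.5-fold) and Nars2 (log2 −4.08, −9.39 to −1.57) were lower.

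T-like cells of the combination library came mainly from cluster 1 (1096 of 1779) and those with MRTX1133 from cluster 4 (471 of 832). All 14 cytotoxic effector genes were lower, median −1.73 (−1.87 to −1.61). Gzma at −3.21, Ccl3 at −3.06, Gzmb at −2.69 and Ifng at −2.69 had the largest folds. The median lay below all 10000 random lists, and without naive-like and unnamed subclusters it was −1.16. 9 of 10 T cell checkpoint genes were lower, median −1.63 (−1.74 to −1.496). 8 of 9 naive and memory T genes were higher, median 1.32 (1.22 to 1.504). 19 of 22 interferon response genes were higher, median 1.51 (1.44 to 1.90). Medians were −0.80 (−0.93 to −0.69) for regulatory T (9 of 11 lower), −0.15 (−0.24 to −0.07) for costimulation (5 of 7 lower), −0.67 (−0.89 to −0.54) for cell cycle (19 of 22 lower) and −1.22 (−1.31 to −1.14) for dissociation stress (9 of 12 lower). Without those subclusters the checkpoint median was −0.82, and regulatory T turned sign to 0.02 (−0.11 to 0.15). Ctla4 was at −0.63 (−0.70 to −0.57), Pdcd1 at −1.72 (−1.85 to −1.60) and Fasl at −1.59 (−1.80 to −1.38). Ralyl (log2 6.26, 3.74 to 11.58), Ifit3b (log2 6.17, 4.61 to 8.46) and Trim30c (70.9-fold) were higher, and the granzyme gene Gzmf (log2 −8.60, −13.91 to −6.11), Paqr3 (12.8-fold) and Sorcs1 (12.8-fold) were lower.

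B-like cells of the combination library came mainly from cluster 2 (1141 of 1308) and those with MRTX1133 from cluster 15 (272 of 322). 18 of 20 interferon response genes were higher, median 1.72 (1.54 to 2.17). 6 of 11 B cell activation genes were lower, median −0.41 (−0.82 to 0.12, mean 0.24). The median was 1.20 (1.08 to 1.41) for cell cycle (22 of 22 higher). Fas was at 1.45 (0.83 to 2.14).

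The same combination was set against anti-CTLA4 alone, to ask what the inhibitor added. T-like cells were 41.9% of immune cells against 14.1%, a difference of 27.8 points (25.8 to 29.7), and CD8-like cells per myeloid cell were 10.2-fold as many (7.58 to 13.8), or 2.73-fold (1.88 to 3.97) without the subcluster led by acinar genes, with Cd8a in T-like cells at −0.13 (−0.27 to 0.00). RAS-MAPK output genes were lower in epithelial-like cells, and MHC class II and interferon response genes higher. Cytotoxic genes were lower in T-like cells. Fas was at 1.35 (0.98 to 1.71) and Kras at −0.31 (−0.41 to −0.21) in epithelial-like cells, but Kras at 0.22 (0.11 to 0.33) without the duct-like cluster.

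Epithelial-like cells numbered 360 and 1057, with cluster 17 holding 264 of the first and cluster 3 holding 785 of the second, and the median gene stood at 0.26. 14 of 15 RAS-MAPK output genes were lower, median −1.25 (−1.46 to −1.09, −1.51 relative). Dusp4 at −4.08, Spry4 at −3.27, Dusp5 at −3.18 and Fosl1 at −2.90 differed most, and Ccnd1 at 0.68 went against the median. The median lay below all 10000 random lists. All 11 MHC class I genes were higher, median 1.45 (1.38 to 1.56, 1.19 relative). All 7 MHC class II genes were higher, median 2.18 (2.09 to 2.23, 1.93 relative). All 22 interferon response genes were higher, median 2.17 (2.05 to 2.26, 1.91 relative). All 15 glycolysis and hypoxia genes were lower, median −1.39 (−1.51 to −1.37, −1.65 relative). 10 of 11 mesenchymal genes were lower, median −1.51 (−1.96 to −1.26, −1.76 relative). Medians were 0.46 (0.36 to 0.58, 0.21 relative) for cell cycle (19 of 22 higher), −0.63 (−1.16 to −0.32, −0.88 relative) for tumour cytokine (10 of 13 lower), 0.08 (−0.00 to 0.28, but −0.17 relative) for death receptor (4 of 8 higher) and −0.32 (−0.40 to −0.27, −0.57 relative) for classical epithelial (10 of 13 lower). Without cluster 17, which left 96 cells, medians were −1.38 (−1.67 to −1.23) for RAS-MAPK output, with Ccnd1 at −0.77, 1.11 for cell cycle, −0.94 for glycolysis and hypoxia, −0.76 for mesenchymal, 0.03 for tumour cytokine and 0.04 for classical epithelial genes, the last 2 of opposite sign. Thinning turned the cell cycle median to −0.09. Obp2b (639-fold), Eprn (log2 8.93, 6.41 to 14.26) and Fam198a (log2 8.83, 6.30 to 14.15) were higher, and the seminal vesicle genes Svs5, Svs4 and Svs2 were lower, at least 2479.6-fold, at least 1199.9-fold and at least 593-fold.

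Fibroblast-like cells (367 and 239) came mainly from cluster 9 in each library. 10 of 11 myofibroblastic CAF genes were lower, median −1.77 (−1.89 to −1.67, −1.94 relative). Medians were −1.71 (−1.89 to −1.49, −1.89 relative) for antigen-presenting CAF (7 of 7 lower) and 1.21 (1.06 to 1.34, 1.04 relative) for interferon response (19 of 22 higher). Akr1cl (log2 9.99, 7.50 to 15.29), Nr5a2 (at least 339-fold) and Cyp11a1 (190.4-fold) were higher, and Serpina3m (log2 −6.55, −11.86 to −4.06), the B cell chemokine gene Cxcl13 (78.2-fold) and Fgf23 (log2 −5.38, −10.70 to −2.86) were lower. Kras was at 0.93.

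In macrophage-like cells (412 and 681), medians were −1.17 (−1.24 to −1.06) for tissue-repair macrophage (11 of 14 lower), 1.46 (1.44 to 1.47) for MHC class II (7 of 7 higher) and 1.51 (1.44 to 1.59) for interferon response (20 of 22 higher). Retnla (79.9-fold), Lyz1 (28.2-fold) and Clec4b1 (22.8-fold) were higher, and Frg2f1 (log2 −5.62, −8.67 to −3.76), the scavenger receptor gene Marco (28.8-fold) and Il10 (23.9-fold) were lower. Neutrophil-like cells came mainly from cluster 7 in the combination library (149 of 245) and cluster 8 with anti-CTLA4 (585 of 1114). All 22 interferon response genes were higher, median 2.04 (1.73 to 2.24, 2.20 relative). Gbp2 (12.1-fold) and Gbp5 (9.76-fold), interferon-induced GTPases, and Slc36a3os (6.61-fold) were higher, and Nars2 (log2 −5.47, −10.77 to −2.98), Fam71f2 (35.8-fold) and Klhl7 (log2 −5.09, −10.39 to −2.60) were lower.

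T-like cells of the combination library came mainly from cluster 1 (1096 of 1779) and those with anti-CTLA4 from cluster 4 (172 of 385). 13 of 14 cytotoxic effector genes were lower, median −1.02 (−1.19 to −0.84). Gzma at −1.71, Ifng at −1.67, Gzmb at −1.47 and Tnf at −1.45 were furthest from 0, and Ccl4 at 0.09 (−0.08 to 0.27) went against the median. All 10 T cell checkpoint genes were lower, median −0.82 (−0.96 to −0.68). 20 of 22 interferon response genes were higher, median 2.28 (2.04 to 2.52). Medians were 1.35 (1.25 to 1.49) for naive and memory T (8 of 9 higher), −0.15 (−0.24 to −0.03, mean 0.21) for costimulation (4 of 7 lower), −0.55 (−0.69 to −0.43) for regulatory T (10 of 11 lower), −0.66 (−0.98 to −0.33) for cell cycle (16 of 21 lower) and −2.04 (−2.12 to −1.97) for dissociation stress (10 of 12 lower). Ctla4 was at −0.31 (−0.38 to −0.22), Pdcd1 at −1.07 (−1.22 to −0.92) and Fasl at −1.12 (−1.37 to −0.87). Without naive-like and unnamed subclusters the cytotoxic effector median was −0.48, checkpoint −0.26, naive and memory 0.73 and regulatory T −0.31. Oas2 (log2 7.55, 5.06 to 12.86), Oas3 (log2 6.89, 5.03 to 9.94) and Ifi44 (log2 6.51, 4.02 to 11.82), interferon-induced genes, were higher, and the granzyme genes Gzmf (log2 −8.33, −13.64 to −5.83), Gzme (at least 89.8-fold) and Gzmd (at least 51.8-fold) were lower. B-like cells came mainly from cluster 2 in the combination library (1141 of 1308) and cluster 19 with anti-CTLA4 (250 of 336). Their interferon response median was 2.38 (2.12 to 2.78, 2.51 relative) with 19 of 20 higher and cell cycle 3.20 (2.85 to 3.51, 3.34 relative) with 22 of 22 higher, with Fas at 2.44.

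In KPC2, the libraries KPC2_VehIso, KPC2_RMC6236, KPC2_RMC6236_antiCTLA4 and KPC2_RMC6236_antiPD1 held total counts of 89709859, 78904460.0, 50237602 and 61850313, with median counts per barcode of 5449.5, 6586, 6152 and 7379. Filters kept 92.8%, 92.6%, 97.9% and 98.1% of barcodes, and 5976, 5759, 6343 and 5178 cells were analysed. Acinar RNA took 33.1, 44.7, 62.3 and 157 CPM, haemoglobin 3650.78, 2584.68, 1182.71 and 214 CPM, and dissociation stress genes 2251.26, 1908.04, 792.0 and 2278.26 CPM of all cells. As the sort was for CD45, a leukocyte marker, epithelial-like and fibroblast-like cells were those it let through. Epithelial-like cells were 9.77%, 5.05%, 0.0158% (1 cell) and 0.502% (26 cells) of cells, and unnamed clusters held 1.19%, 2.66%, 4.67% and 2.57%. Cells with Y-linked transcripts and cells with Xist occurred in every library, and whether several mice were pooled is not stated. Of T-like cells with only 1 of these kinds, those with Y-linked transcripts were 80.2%, 88.5%, 68.9% and 13.95% in the 4 libraries, at median depths of 7110.5, 7870.5, 7834 and 8813 counts. Epithelial-like cells had Y-linked transcripts alone in 5.11% (vehicle) and 4.40% (RMC6236) of such cells.

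RMC6236 against vehicle in KPC2 asked how immune cells differed under the RAS inhibitor. T-like cells were 24.3% of immune cells (1262 of 5191) against 16.0% (834 of 5201), a difference of 8.28 points (6.74 to 9.81). CD8-like cells were 21.8% against 4.44% of T-like cells and 7.23-fold as many per myeloid cell (5.10 to 10.2), but Cd8a in T-like cells was at 0.35 (0.23 to 0.46). Unnamed KPC2 subclusters of 920.0 and 562 cells had Cd8b1 at 707 and 782 CPM, against 632 in the CD8-like one, so the CD8-like share did not count all cells with CD8 transcripts. Cytotoxic effector genes were higher in T-like cells, among them Gzma and Ifng. The epithelial-like cells that passed the sort had far lower cell cycle genes, Kras at −0.26 (−0.29 to −0.24) and Fas at 1.38 (0.68 to 2.08).

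B-like cells were 27.9% against 41.8% of immune cells, neutrophil-like 21.4% against 22.2%, macrophage-like 4.82% against 6.75%, monocyte-like 9.79% against 5.98%, natural killer-like 3.43% against 1.44%, mast-like 2.87% against 0.9998% and dendritic-like 3.43% against 3.48%. CD4-like, regulatory, naive-like and unnamed cells were 14.7%, 14.9%, 18.3% and 30.3% of T-like cells with RMC6236 and 5.40%, 14.03%, 27.5% and 48.7% with vehicle. The regulatory cells included 11 and 14 of a subcluster led by haemoglobin and macrophage genes, with Foxp3 at 41.8 CPM against 389 in the largest regulatory one. With doublets kept, the T-like share differed by 4.49 points.

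T-like cells with RMC6236 came mainly from cluster 6 (521) and those with vehicle from clusters 3 (273) and 4 (268). 13 of 14 cytotoxic effector genes were higher, median 1.77 (1.53 to 2.04). Ccl3 at 4.79, Ccl4 at 3.60, Gzma at 3.005 and Ifng at 2.99 lay furthest from 0, and Prf1 at −0.20 (−0.45 to 0.06) lay against the median. The median lay above all 10000 random lists, and it was 1.92 in cells with Y-linked transcripts alone and 0.50 in cells with Xist alone. 9 of 10 T cell checkpoint genes were higher, median 0.98 (0.82 to 1.18). 6 of 7 T cell costimulation genes were higher, median 0.52 (0.45 to 0.60). All 9 naive and memory T genes were lower, median −0.76 (−0.80 to −0.70). 9 of 11 regulatory T genes were higher, median 0.37 (0.20 to 0.45). Medians were 0.23 (0.12 to 0.41) for interferon response (15 of 21 higher) and 0.84 (0.48 to 1.01) for cell cycle (17 of 20 higher). Without naive-like and unnamed subclusters, the cytotoxic effector median was 1.40 and checkpoint 0.19 (0.01 to 0.43), and regulatory T turned sign to −0.68. Ctla4 was at −0.12 (−0.23 to −0.00), Pdcd1 at 1.09 (0.90 to 1.29) and Fasl at 1.26 (0.96 to 1.58). Jchain, the joining chain of secreted antibodies (276-fold), the adrenergic receptor gene Adrb1 (log2 5.14, 2.60 to 10.47) and Plekhf1 (log2 5.09, 2.55 to 10.42) were higher, and Syt6 (9.94-fold), Trnp1 (8.44-fold) and Vwa3b (4.92-fold) were lower. Jchain is a plasma cell transcript, also named below in neutrophil-like cells, and a T subcluster of 28 cells was led by Igkc and Jchain, so RNA of plasma cells or doublets with them was not excluded.

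Epithelial-like cells numbered 291 and 584, and the median gene stood at 0.15. 10 of 15 RAS-MAPK output genes were lower, median −0.19 (−0.27 to −0.16, −0.34 relative). Dusp5 at −1.93, Fosl1 at −1.18, Dusp4 at −1.15 and Ier3 at −1.07 had the largest folds, and Spry4 at 0.03 (−0.14 to 0.19), Spred1 at 0.12, Etv5 at 0.35, Phlda1 at 0.71 and Epha4 at 0.996 lay against the median. All 22 cell cycle genes were lower, median −4.18 (−4.40 to −3.84, −4.33 relative). Ube2c at −5.91, Ccnb1 at −5.86 (−7.07 to −4.87), Ccnb2 at −5.40 and Cenpf at −5.40 differed most. All 11 MHC class I genes were higher, median 1.02 (0.87 to 1.11, 0.86 relative). 20 of 21 interferon response genes were higher, median 1.35 (1.18 to 1.59, 1.20 relative). All 15 glycolysis and hypoxia genes were lower, median −1.08 (−1.15 to −1.04, −1.23 relative). 8 of 13 tumour cytokine genes were lower, median −0.40 (−0.61 to 0.19, −0.55 relative, mean 0.03). 10 of 13 classical epithelial genes were higher, median 0.69 (0.65 to 0.75, 0.53 relative). Medians were 0.51 (0.41 to 0.64, 0.36 relative) for MHC class II (7 of 7 higher), 0.09 (−0.05 to 0.28, but −0.06 relative) for death receptor (5 of 8 higher) and −0.69 (−0.88 to −0.59, −0.84 relative) for mesenchymal (9 of 11 lower). Thinning turned the MHC class II median to −0.28. In fibroblast-like cells (50 and 43), the myofibroblastic CAF median was −2.73 (−2.93 to −2.46) with 9 of 10 lower, inflammatory CAF 1.17 (0.70 to 1.46) with 8 of 11 higher, antigen-presenting CAF 1.54 (1.36 to 1.71) with 7 of 8 higher and interferon response 1.90 (1.67 to 2.18) with 21 of 21 higher, with Kras at −0.05.

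In macrophage-like cells (250 and 351), Cxcl13 (28.5-fold), Scart1 (at least 27.6-fold) and Procr (log2 4.23, 2.62 to 6.55) were higher, and Adamdec1 (29.7-fold), Spon1 (28.5-fold) and Mt3 (log2 −4.36, −6.68 to −2.74) were lower. In neutrophil-like cells (1109 and 1153), Jchain (37.7-fold), the granule enzyme gene Mpo (26.5-fold) and H2ac8 (10.5-fold) were higher, and Bcl2l15 (54.0-fold), Hspa1a (32.1-fold) and Hspa1b (20.8-fold), heat shock genes, were lower. In B-like cells (1447 and 2175), Slit3 (4.81-fold), S1pr3 (3.61-fold) and Crisp3 (2.84-fold) were higher, and Ston1 (10.2-fold), Fkbp5 (3.60-fold) and Pik3ip1 (3.27-fold) were lower, with Fas at −0.14 (−0.69 to 0.41).

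Adding anti-CTLA4 to RMC6236 in KPC2 was compared with RMC6236 alone. T-like cells were 38.9% of immune cells (2323 of 5978) against 24.3%, a difference of 14.5 points (12.8 to 16.2), or 55.9 without B-like and plasma-like cells, and B-like cells were 55.5% against 27.9%. Neutrophil-like, macrophage-like and monocyte-like cells were 1.22%, 0.351% and 0.853% against 21.4%, 4.82% and 9.79%. Naive-like cells were 46.0% against 18.3% of T-like cells and CD8-like cells 1.76% against 21.8%, but Cd8a was at −0.24 (−0.32 to −0.16), and unnamed subclusters with Cd8b1 lay outside the CD8-like cells. In T-like cells, cytotoxic effector, checkpoint and regulatory T genes were lower and a set of interferon response genes was higher.

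Natural killer-like cells were 0.970% against 3.43% of immune cells, mast-like 0.117% against 2.87% and dendritic-like 0.519% against 3.43%. CD4-like, regulatory and unnamed cells were 3.79%, 7.36% and 41.1% of T-like cells with the antibody, and CD8-like cells were 1.92-fold as many per myeloid cell (1.33 to 2.78). Epithelial-like lists were not computed, as the combination library held 1 such cell.

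T-like cells of the combination library came mainly from clusters 3 (836) and 4 (817), with 219 in cluster 17, and those with RMC6236 from cluster 6 (521), and the median gene stood at −0.40. All 14 cytotoxic effector genes were lower, median −2.26 (−2.37 to −2.06, −1.86 relative). Ccl3 at −4.57, Fasl at −2.97, Ifng at −2.65 and Cxcr6 at −2.59 were furthest from 0. Without naive-like and unnamed subclusters the median was −0.65, checkpoint −1.15 and regulatory T −0.24, and the cytotoxic median was −2.30 in cells with Y-linked transcripts alone and −0.71 in cells with Xist alone. All 10 T cell checkpoint genes were lower, median −2.73 (−2.95 to −2.55, −2.33 relative). 6 of 7 T cell costimulation genes were lower, median −1.15 (−1.20 to −1.04, −0.75 relative). 8 of 9 naive and memory T genes were higher, median 0.73 (0.67 to 0.80, 1.12 relative). All 11 regulatory T genes were lower, median −1.86 (−2.03 to −1.67, −1.46 relative). 14 of 21 interferon response genes were higher, median 0.24 (0.14 to 0.38, 0.64 relative). Ifit3 at 3.38, Rsad2 at 3.32, Isg15 at 2.84 and Ifit1 at 2.61 lay furthest from 0, and against the median stood Irf1 at −0.26, Stat2 at −0.06 (−0.30 to 0.18), Gbp3 at −0.64, Gbp4 at −0.08 (−0.24 to 0.07), Gbp5 at −0.33, Gbp7 at −0.40 and Cxcl10 at −0.64. The median was −1.28 (−1.57 to −1.03, −0.88 relative) for cell cycle (20 of 20 lower). Ctla4 was at −1.12 (−1.23 to −1.01), Pdcd1 at −3.38 (−3.62 to −3.15) and Fasl at −2.97 (−3.29 to −2.66). Ifit3 (10.4-fold), Ifit3b (10.2-fold) and Mx2 (7.87-fold), interferon-induced genes, were higher, and Atp2b2 (41.3-fold), Tnc (37.3-fold) and the enkephalin precursor gene Penk (36.7-fold) were lower.

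B-like cells of the combination library came mainly from cluster 0 (2146 of 3318) and those with RMC6236 from cluster 1 (809 of 1447), and the median gene stood at −0.25. 12 of 17 interferon response genes were lower, median −0.27 (−0.36 to −0.13, −0.02 relative). Irf7 at 1.10, Gbp7 at −0.95, Gbp3 at −0.91 and Ifit2 at −0.62 had the largest folds, and against the median stood Ifit3 at 0.76 (−0.89 to 2.81), Isg15 at 0.53 (−0.12 to 1.23), Gbp2 at 0.25 (−0.34 to 0.86) and Bst2 at 0.39. A stricter cell filter turned that median to 0.25. An unnamed cluster of 408 cells led by Ifit3, with 66.2% of its cells in the combination library, lay outside the B-like class. Fas was at 0.56 (0.10 to 1.06). Or52ac1 (6.80-fold), the sterol synthesis gene Msmo1 (3.11-fold) and Clps (2.96-fold), an acinar gene, were higher, and Slit3 (9.99-fold), Agbl1 (5.89-fold) and Tenm4 (2.81-fold) were lower.

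Myeloid classes of the combination library were small. In macrophage-like cells (21 and 250), medians were −1.01 (−1.37 to −0.56) for inflammatory macrophage (8 of 10 lower) and −1.41 (−1.72 to −1.04) for tissue-repair macrophage (11 of 14 lower). In monocyte-like cells (51 and 508), the median was −1.17 (−2.12 to −0.89) for inflammatory macrophage (9 of 11 lower). In neutrophil-like cells (73 and 1109), all 12 neutrophil activation genes were lower, median −1.40 (−1.62 to −1.21, −1.17 relative). 8 of 10 neutrophil maturation genes were higher, median 1.89 (1.70 to 2.01, 2.12 relative).

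Adding anti-PD1 to RMC6236 in KPC2 was compared with RMC6236 alone. T-like cells were 19.4% of immune cells (959 of 4943) against 24.3%, a difference of −4.91 points (−6.51 to −3.30). It was −18.2 points (−20.3 to −16.1) in cells with Y-linked transcripts alone and −1.66 (−6.46 to 2.82) in cells with Xist alone. CD8-like cells were 4.28% against 21.8% of T-like cells and 0.139-fold as many per myeloid cell (0.0992 to 0.194), but Cd8a in T-like cells was at −0.27 (−0.36 to −0.17), and unnamed subclusters with Cd8b1 lay outside the CD8-like cells. Cytotoxic effector genes were lower in T-like cells and naive and memory genes higher. In cells with Y-linked transcripts alone, which were 107 and 935 T-like cells, the cytotoxic effector median was 0.16 (−0.05 to 0.31), and in cells with Xist alone, 660.0 and 122, it was −1.05 (−1.33 to −0.82).

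B-like cells were 31.6% against 27.9% of immune cells, neutrophil-like 22.9% against 21.4%, macrophage-like 5.06% against 4.82%, monocyte-like 12.7% against 9.79%, natural killer-like 1.78% against 3.43%, mast-like 0.688% against 2.87% and dendritic-like 3.803% against 3.43%. CD4-like, regulatory, naive-like and unnamed cells were 4.07%, 11.2%, 36.8% and 43.7% of T-like cells with anti-PD1. The 4 settings fixed beforehand put the difference in T-like share between −2.87 and −0.61 points, and with doublets kept the interval spanned 0 (−2.09 to 0.87).

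T-like cells with anti-PD1 came mainly from clusters 3 (327) and 4 (306), those with RMC6236 from cluster 6 (521), and the median gene stood at −0.25. 13 of 14 cytotoxic effector genes were lower, median −1.47 (−1.59 to −1.30, −1.22 relative). Ifng at −2.497, Ccl4 at −2.44, Cxcr6 at −2.13 and Ccl3 at −2.01 differed most, and Prf1 at 0.10 (−0.14 to 0.34) went against the median. Without naive-like and unnamed subclusters the median was −0.69 and checkpoint −0.46, and the regulatory T median turned sign to 0.19. All 10 T cell checkpoint genes were lower, median −1.45 (−1.58 to −1.25, −1.20 relative). 7 of 9 naive and memory T genes were higher, median 0.63 (0.60 to 0.70, 0.88 relative). 9 of 11 regulatory T genes were lower, median −0.94 (−1.13 to −0.80, −0.70 relative). Medians were −0.86 (−0.94 to −0.74, −0.61 relative) for costimulation (6 of 7 lower), 0.50 (0.40 to 0.59, 0.75 relative) for interferon response (15 of 22 higher) and −0.64 (−0.98 to −0.43, −0.39 relative) for cell cycle (18 of 21 lower). Ctla4 was at −0.26 (−0.37 to −0.14), Pdcd1 at −1.97 (−2.18 to −1.75) and Fasl at −1.64 (−1.94 to −1.35). Dtx1 (4.995-fold), Rasal1 (4.18-fold) and Zfp804b (3.79-fold) were higher, and Or13a27 (log2 −4.81, −7.11 to −3.22), Klrh1 (at least 16.7-fold) and Arnt2 (9.52-fold) were lower.

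In macrophage-like cells, Gdf3 (4.48-fold), Adam22 (3.42-fold) and Fhad1 (3.35-fold) were higher, and Scart1 (log2 −4.55, −6.85 to −2.96), the matrix gene Dcn (at least 14.9-fold) and Marco (12.6-fold) were lower. In neutrophil-like cells (1131 and 1109), Nos2 (10.5-fold), Hspa1a (9.82-fold) and Gdf15 (6.10-fold), a stress cytokine, were higher, and Mpo (log2 −7.30, −12.61 to −4.79), Elane (33.5-fold) and Zfp804a (4.20-fold) were lower. In B-like cells (1564 and 1447), the kinase gene Cdk8 (2.15-fold) was higher, no gene met the rule for lower, and Fas was at 0.16 (−0.39 to 0.72). Epithelial-like cells (26 and 291) had medians of −0.21 (−0.36 to −0.02) for RAS-MAPK output (11 of 15 lower), 0.27 (−0.05 to 0.57) for cell cycle (12 of 19 higher), −0.90 (−1.14 to −0.69) for interferon response (15 of 20 lower) and −1.15 (−1.51 to −0.79) for tumour cytokine (8 of 10 lower). The 7 other medians lay between −0.62 and 0.08, with Kras at −0.09 (−0.18 to −0.00) and Fas at −0.64 (−3.73 to 1.31).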

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

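The tests without the duct-like cluster, of UMIs per cell, of added naive lymphocytes and by sex-linked UMIs were chosen only after the result was seen, as was the bound for the stricter filter, a setting fixed beforehand.

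The interferon response median in B-like cells had opposite signs in the 2 models when anti-CTLA4 was added. The median log2 fold was 1.72 (1.54 to 2.17) in KPC3, on MRTX1133, and −0.27 (−0.36 to −0.13) in KPC2, on RMC6236. This was 1 of 13 lists with opposite signs in the 2 models, each from 1 library per group, and the difference was not tested. Relative to the median gene the KPC2 value was −0.02, and under the stricter filter it was 0.25.

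In KPC3, RAS-MAPK output genes in epithelial-like cells stood at −1.25 for the combination against anti-CTLA4. Duct-like cells of the host could lower the list, but without that cluster the median was −1.38 (−1.67 to −1.23), past 0.5 of the full value. A first depth test, thinning to 1000 UMIs, gave −0.99 (−1.53 to −0.59) and did not decide. A second, chosen later, gave a median UMI ratio of 0.809 (anti-CTLA4 over combination) outside that cluster, which argues against depth for −1.38. With the cluster, medians were 30627 and 9578, so depth stays open for −1.25. Inhibition by MRTX1133 stays open as untested. MRTX1133 alone stood at −0.07 against anti-CTLA4, and the combination at −1.18 against MRTX1133 though both received it. Host sex, which differed, and an exchange of labels also stay open.

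The T-like share was higher in KPC1 MRTX1133, KPC3 MRTX1133 with anti-CTLA4 and KPC2 RMC6236 with anti-CTLA4, in each case with more naive-like and B-like cells. Naive lymphocytes from lymphoid tissue could raise the share without more effector cells. In KPC1, CD8-like cells per myeloid cell were 23.9-fold as many (19.0 to 30.1), which argues against naive cells alone in an otherwise unchanged tumour. For KPC3 the ratio was 1.60, but 0.421 without a subcluster led by acinar genes, and for KPC2 it was 1.92, between the bounds of 1.5 and 2, so added naive lymphocytes and the treatment cannot be told apart in these pairs. The KPC3 difference was 14.4 points under the stricter filter, which restores no lost cells, so depth stays open. The tissue sampled, CD8-like cells included, stays open in each pair.

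In KPC2, cytotoxic effector genes in T-like cells stood at −1.47 with anti-PD1 added. Whether several mice were pooled per library is not stated. A change in the mix of sexes in the library, as the whole account, would bring the list toward 0 within each kind of cell. In cells with Y-linked UMIs alone the median was 0.16 (−0.05 to 0.31), as that account needs. In cells with Xist alone it stayed at −1.05 (−1.33 to −0.82), past 0.5 of the full value, which argues against the mix as the whole account. The bound first written asked for a smaller value in either kind alone and was too loose. A mix as part of the account, and a response to anti-PD1, stay open.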

How the results depend on the processing

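The splits by sex-linked UMIs, the epithelial-like values without the duct-like cluster, the CD8-like ratios without subclusters led by acinar genes, the T-like shares without B-like and plasma-like cells, the T-like lists without naive-like and unnamed subclusters, and all settings of lists other than the design results were chosen only after the result was seen. For the 14 design results, 64 values under other settings lay within the counting interval of the result, 54 lay outside it, and 1 reversed a result whose interval excluded 0. For 236 other results the numbers were 407, 313 and 29. Depth limits the KPC3 combination most, with a median of 2921.5 UMIs per barcode. For each value below, the cause was not tested.

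With doublets kept, the difference in T-like share was 45.3 points in KPC1, 24.7 for the KPC3 combination against anti-CTLA4, 4.49 for RMC6236 against vehicle, 19.6 with anti-CTLA4 added to RMC6236 and −0.61 (−2.09 to 0.87) with anti-PD1 added. The cytotoxic effector median was −2.12 for the KPC3 combination against MRTX1133, 2.32 for RMC6236, −2.73 with anti-CTLA4 and −1.25 with anti-PD1.

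At Leiden resolution 2, the T-like share differed by 44.3 points in KPC1, 5.88 for RMC6236 and −2.77 with anti-PD1. The cytotoxic effector median was −2.04 for the KPC3 combination, 2.31 for RMC6236, −2.59 with anti-CTLA4 and −2.02 with anti-PD1. With classes assigned cell by cell, the share differed by 43.6 points in KPC1, 12.1 for the KPC3 combination against MRTX1133, 21.1 against anti-CTLA4 and −2.64 with anti-PD1, and the cytotoxic median of the KPC3 combination was −1.60.

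Under the stricter cell filter, the share differed by 14.4 points for the KPC3 combination against MRTX1133, 25.4 against anti-CTLA4, 6.03 for RMC6236 and −2.87 with anti-PD1. The cytotoxic median was 2.38 for RMC6236 and −2.74 with anti-CTLA4. Reversed were interferon response in macrophage-like cells of KPC1 at −0.31, tissue-repair genes in KPC3 MRTX1133 against anti-CTLA4 at 0.0567, interferon response in B-like cells with anti-CTLA4 in KPC2 at 0.25 and dissociation stress in monocyte-like cells with anti-PD1 at −0.0361.

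With each cell thinned to 1000 UMIs, the RAS-MAPK output median was −0.36 in KPC1, −0.29 in KPC3 MRTX1133 against anti-CTLA4 and −0.99 for the combination against anti-CTLA4, and the cytotoxic median with anti-CTLA4 in KPC2 was −1.85. Reversed in KPC1 were tumour cytokine genes at −0.14 and glycolysis and hypoxia genes at −0.0116. Reversed in KPC3 MRTX1133 against anti-CTLA4 were classical epithelial genes at 0.0823, mesenchymal genes at −0.17, tissue-repair macrophage genes at 0.0466 and interferon response in B-like cells at −0.10. Neutrophil maturation reversed to −0.0578 for the combination against MRTX1133, and epithelial cell cycle to −0.0858 against anti-CTLA4. In KPC2, MHC class II in epithelial-like cells reversed to −0.28 for RMC6236, and with anti-PD1 neutrophil maturation to −0.10 and neutrophil interferon response to 0.00654.

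Under median-of-ratios scaling, the RAS-MAPK output median was −0.45 in KPC1 and −1.51 for the KPC3 combination against anti-CTLA4, and the cytotoxic median −1.86 with anti-CTLA4 and −1.22 with anti-PD1. Reversed were KPC1 tumour cytokine genes at −0.16, glycolysis and hypoxia genes at −0.21, and dissociation stress in T-like cells with anti-CTLA4 in KPC2 at 0.0103. CPM without mitochondrial, ribosomal and haemoglobin genes gave cytotoxic medians of −1.95 with anti-CTLA4 and −1.25 with anti-PD1.

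Without the duct-like cluster, reversed for the KPC3 combination against MRTX1133 were cell cycle at 0.0756, classical epithelial genes at 0.137 and Kras at 0.34, and against anti-CTLA4 tumour cytokine genes at 0.0344, classical epithelial genes at 0.0432 and Kras at 0.22. Without subclusters led by acinar genes, the log2 ratio of CD8-like to myeloid cells reversed to −1.25 for the combination against MRTX1133.

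Without B-like and plasma-like cells, the share differed by 74.6 points in KPC1, 40.1 for the KPC3 combination against MRTX1133, 51.1 against anti-CTLA4, 6.39 for RMC6236 and 55.9 with anti-CTLA4 in KPC2. Without naive-like and unnamed subclusters, the cytotoxic median was −1.16 for the KPC3 combination, 1.40 for RMC6236, −0.65 with anti-CTLA4 and −0.69 with anti-PD1, and the regulatory T median reversed to −0.27 for KPC3 MRTX1133 against anti-CTLA4, 0.0210 for the KPC3 combination against MRTX1133, −0.68 for RMC6236 and 0.19 with anti-PD1. The mix of subsets among the cells left still differed between libraries. In cells with Y-linked UMIs alone, the share differed by 9.82 points with anti-CTLA4 and −18.2 with anti-PD1, and the cytotoxic median with anti-PD1 reversed to 0.16. In cells with Xist alone, the share differed by 12.5 points for RMC6236, 19.3 with anti-CTLA4 and −1.66 with anti-PD1, and the cytotoxic median was 0.50, −0.71 and −1.05.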

Other observations

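All clusters described here were picked after their values were seen, and no explanation was tested for them.

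A KPC1 cluster led by Dkk2, with Grem1, was left unnamed by the rule on top genes and was 11.5% of cells (10.9 to 12.2) in the vehicle library and 4.47% (4.004 to 4.97) in the MRTX1133 library. A KPC1 cluster led by Ctsk, with the osteoclast genes Acp5 and Ocstamp, held 210.0 vehicle cells and 3 MRTX1133 cells. In KPC2, a cluster led by Ifit3 held 270.0 cells with anti-CTLA4 added, 4.26% of that library, against 28, 41 and 69 cells with RMC6236 alone, vehicle and anti-PD1 added, and a T-like cluster led by Ifit1 held 219 against 7, 5 and 34.

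Genes of other organs appeared in several libraries. Steroid synthesis genes were high in fibroblast-like cells of the KPC3 combination, and a KPC1 cluster of 21 cells led by Inha, with Akr1cl and Hsd3b1, was seen only with MRTX1133. Seminal vesicle genes were seen in epithelial-like cells with anti-CTLA4 and muscle genes in those with MRTX1133 in KPC3. An adipocyte-type cluster led by Cfd held 27 cells, all in the anti-CTLA4 library. A KPC3 cluster with Ccr3 and Alox15, genes of eosinophils, held 124, 79 and 0 cells with anti-CTLA4, MRTX1133 and the combination, at median depths of 641 and 648 UMIs, and 0 of 6345 cells allows up to 0.0581%.

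Xist and Y-linked UMIs put T-like cells of the KPC3 combination with one sex and those of the other KPC3 libraries with the other, and whether labels were exchanged is not known. In KPC2, cells with Y-linked UMIs alone were 10.4% of B-like and 75.0% of neutrophil-like cells with anti-PD1 added, and 89.3% and 89.2% with RMC6236 alone.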
